A study of Mus musculus with 18 samples.

How the data were processed

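Total RNA was sequenced from BMC, an immortalised line of mouse brown preadipocytes, after differentiation into brown adipocytes. Per the labels' protocols, differentiation began with a cocktail of 20 nM insulin, 1 nM triiodothyronine, 1 µM dexamethasone, 0.125 mM indomethacin and 0.5 mM isobutylmethylxanthine. Norepinephrine was then used at 1 µM on day 7, and each cell pellet served both proteomics and transcriptomics. Libraries were made from 250 ng of RNA with a total RNA kit that keeps the strand and depletes ribosomal RNA by the AnyDeplete method. They were sequenced as 52-base read pairs, per the labels. The labels give 3 groups (0 h, 4 h and 24 h), 6 libraries in each with replicate numbers 1 to 6, and a single batch, numbered 1, for all 18. They do not say whether the 6 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

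The deposited table holds expected counts per gene, estimated by salmon and merged over libraries, as its name and the labels record. It covers 45706 genes, of which 26331 had a count in any library, and 27.4% of the values above 0 were not whole. The submitters' processing notes name edgeR, limma and the mouse genome build mm10, with no versions. The salmon version, the annotation and the strand setting are not given in the sources used here. Of the gene identifiers, 45143 were found in GENCODE M21, the mm10 annotation used for positions. Salmon shares reads between near-identical transcripts, so values of genes with close copies, such as ribosomal protein genes and their pseudogenes, are uncertain. Pairs of overlapping genes on one strand carry the same doubt.

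Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR, with its minimum count of 10 and minimum total of 15, leaving 14788 genes with at least 99.9% of the counts of each library. Libraries were scaled by trimmed mean of M values (TMM), and CPM were computed with the TMM-scaled totals. Log2 CPM used a prior count of 2. Each comparison of labelled times was tested with edgeR's robust quasi-likelihood F-test over all 18 libraries, which share 1 estimate of spread per gene, with time as the model's only factor. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and SE denotes the standard error of a log2 fold change. Intervals of fold changes are 95% intervals from the same model. All p-values are two-sided. Replicates are described by mean ± SD. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

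Before the data were examined, 37 gene lists were written for brown adipocytes, adrenergic signalling, metabolism, stress, other cell types and RNA quality. Of their 1040 entries 1002 matched a gene identifier, and 34 lists had the 5 measured members that a test required. Lists were tested by camera, a competitive test of a list against other genes, with a preset correlation between genes of 0.01. Alternatives were an estimated correlation and fry, which asks whether a list's genes move, on balance, one way and compares them with no other genes. Genes named were fixed by a rule set before the data were examined. They are 16 anchor genes of brown adipocytes whatever their result, and per comparison the 5 genes called with the largest rise and the 5 with the largest fall among those with log2 CPM of at least 3 and groups without overlap. Then come 2 members of each of the 8 leading lists called. Of the genes so chosen, 1 is not reported here. Predicted and mitochondrially encoded genes were left out of the ranking, and any other gene named was chosen after its values were seen.

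The numbers pair the libraries. Deviations from the group means correlated between 0.297 and 0.718 in all 18 pairs of libraries with the same number at different times, above the bound of 0.1 set beforehand. Libraries at different times with numbers 3 apart (1 and 4, 2 and 5, 3 and 6) had a median correlation of 0.569, and those with other numbers a median of -0.270. The pairing comes from the replicate numbers in the titles, which no label ties to a culture or a day. A second model therefore had the replicate number as a block beside time, and its values are given where they change a call. Comparisons between replicate numbers, with time in the model, were added after the data were seen. In them number 1 serves as the reference only because it is the lowest.

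Detection was tested on simulated counts drawn from the real means and library sizes with 200 changed genes. The means were fitted per replicate number, so traits of single libraries, such as 24 h replicate 5, were not simulated. For number 2 against 1 they were averaged over all numbers, without the real differences between numbers. In the comparisons of times, 21 lipolysis genes were also raised by log2 0.50 and left out of the scoring. The shares may thus differ in the real libraries. For 4 h against 0 h the model without the block recovered 34.3% of changes of log2 0.50, 58.2% of log2 1 and 90.9% of log2 2, with 0 false calls. With the block the shares were 71.6%, 80.6% and 98.5%, with 11 false calls among 178. For 24 h against 0 h they were 43.3%, 70.1% and 93.8% without the block, and 76.1%, 92.5% and 100% with it (4 false calls among 182). For 24 h against 4 h they were 38.8%, 61.2% and 90.9%, and 64.2%, 82.1% and 95.5% with the block (14 false calls among 175). Without the block no comparison of times had a false call. For replicate number 2 against 1 the shares were 64.2%, 76.1% and 98.5%, with 14 false calls among 173. Shared 0 h libraries were handled by 20 simulations of unchanged groups and by splitting the 0 h group into 3 and 3.

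Library totals and other measures of composition were compared by exact permutation tests over 924 arrangements, which ignore the pairing by number, adjusted over 18 tests. A sign-flip test within the 6 numbers, added after the data were seen, respects it. Shares of a single library carry 95% Wilson intervals, which cover counting error only, because reads without molecular identifiers are not independent molecules. Library totals ran from 7010742 to 26501223 expected counts. All 45 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.31, so none was taken for a second deposit of another. This sets the libraries against counting noise alone, which repeat preparations of a culture would also exceed, so it does not show that they are separate cultures. Pairs with numbers 3 apart gave a median of 12.6 and the other pairs of a group 54.2. Across times the medians were 9.81 for the same number, 9.16 for numbers 3 apart and 56.9 for the rest, with 4.11 the lowest.

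Alternatives were DESeq2, limma-voom, DESeq2's median-of-ratios (RLE) factors, library totals with no scaling factors, and leaving out mitochondrially encoded genes and ribosomal RNA. That last choice went by annotation and kept Yam1, Gm26917 and Lars2, which resemble ribosomal RNA. A model with the block, added after the data were seen, left these out as well. Others were no low-count filter beyond 1 count, a filter of 5 CPM in 6 libraries, only the 12 libraries of a comparison, a threshold of 0.01, and each library left out in turn. No deposited column was left unused.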

Results

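The 18 libraries profiled RNA of BMC brown adipocytes, fat cells that burn lipid to make heat, before and after norepinephrine. This transmitter of sympathetic nerves acts on beta-adrenergic receptors and starts lipolysis, the release of fatty acids from stored fat. By their labels the libraries form 3 groups of 6, not induced (0 h) and 4 h and 24 h after induction with 1 µM norepinephrine, with replicate numbers 1 to 6 in each. Expected counts totalled 22190293 ± 2462008 per library at 0 h (SD, n = 6), 16223380 ± 5163272 at 4 h and 18018281 ± 7056664 at 24 h. The series design names the question as which transcripts change at each time after lipolysis is induced. The numbers in the titles accounted for a median of 72.0% of a gene's variance across the 18 libraries, and the labelled times for 3.78% (29.4% and 11.8% would follow for random labels). The time labels are thus in doubt, as set out under other observations, and comparisons of labelled times may not measure the response to norepinephrine.

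**Figure D1:**
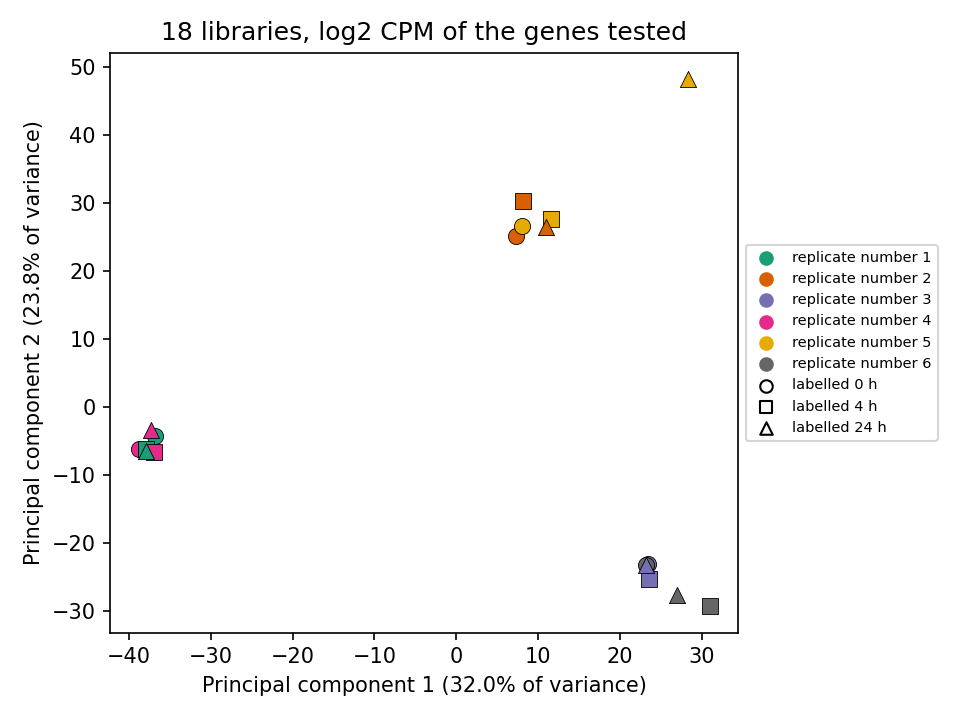
Principal components 1 (32.0% of variance) and 2 (23.8%) of the log2 CPM of the 14788 genes tested, 1 mark per library, with colour for the replicate number and shape for the labelled time. Libraries lie near those of the same number and of the number 3 away, and 24 h replicate 5 lies farthest from the rest along component 2.

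In the libraries labelled 4 h, genes that adrenergic stimulation is known to induce in brown fat differed little in mean level from 0 h beside the spread between libraries. Compared within replicate numbers, the cAMP and immediate early list was slightly higher, as given below. Nr4a1, an immediate early gene encoding a nuclear receptor (chromosome 15, 101254269 to 101274795, mm10), had 33.1 ± 38.6 CPM at 0 h and 43.7 ± 57.5 at 4 h (SD, n = 6). Its log2 fold change was 0.41 (SE 1.03, edgeR adjusted p = 1.00). Ucp1, the uncoupling protein of heat production (chromosome 8, 83290352 to 83298452), had 9.23 ± 6.10 and 9.92 ± 7.25 CPM, log2 0.12 (SE 0.67). Ppargc1a, a coactivator of mitochondrial biogenesis (chromosome 5, 51454250 to 51567726), had 129 ± 10.4 and 123 ± 6.98 CPM, log2 -0.06 (SE 0.07).

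Of the 16 anchor genes 15 were tested at 4 h, and none passed. Their log2 fold changes ran from -0.08 for Gyk, glycerol kinase, to 0.41 for Nr4a1. The genes of triglyceride breakdown had nearly equal levels, with 526 ± 199 and 534 ± 223 CPM for Pnpla2, adipose triglyceride lipase (chromosome 7, 141455198 to 141460743), and 299.7 ± 22.03 and 307 ± 25.1 for Lipe, hormone-sensitive lipase. G0s2, an inhibitor of that first lipase (chromosome 1, 193272161 to 193273217), had 154 ± 129 and 160.1 ± 136 CPM. Adrb3, the beta-3 adrenergic receptor (chromosome 8, 27225776 to 27250616), had 53.7 ± 31.5 and 57.5 ± 33.7 CPM. The log2 fold changes of Dio2 (thyroid hormone activation), Fasn and Scd1 (fatty acid synthesis), Adipoq (adiponectin), Pdk4, Fgf21 and Cidea were 0.04, 0.09, 0.02, 0.02, 0.08, 0.12 and 0.08. Elovl3, a fatty acid elongase, lay below the filter on low counts. With the replicate number as a block the errors were smaller and still no anchor passed. The blocked 95% interval was -0.06 to 0.59 for Nr4a1, -0.10 to 0.29 for Ucp1, -0.14 to 0.02 for Ppargc1a and 0.01 to 0.19 for Adrb3, whose blocked adjusted p was 0.484.

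No gene of the 14788 tested passed at 4 h against 0 h with edgeR, and 173 (1.17%) had an unadjusted p under 0.05. Chance alone would put a share of 0.05 of unchanged genes there. This model, which ignores the pairing by number, was thus conservative, and its count of 0 is weak evidence of no change. DESeq2 and limma-voom also called 0, with 240 and 224 unadjusted. The blocked model called 0 as well, with 1461 unadjusted (9.88%, above that share) and a smallest adjusted p of 0.109. Fos, an immediate early transcription factor picked after its values were seen (chromosome 12, 85473890 to 85477273), was higher at 4 h in all 6 replicate numbers, from 48.2 ± 69.5 to 66.7 ± 96.3 CPM. Its blocked log2 fold change was 0.45 (SE 0.11, adjusted p = 0.238). Groups did not overlap for 10 of the 14788 genes, fewer than the 0.216% of genes that chance gives for 6 against 6. A limma-voom model with the block and library weights, chosen after the data were seen, called 33 genes, 10 higher and 23 lower. Among those higher were the immediate early genes Fos (log2 0.45, adjusted p = 0.0030), Fosb (0.46, 0.0056), Arc (0.30, 0.035), Ier2 (0.30, 0.048) and Egr2 (0.23, 0.048). Without 4 h replicate 3, edgeR called 1 gene, ACEA_U3.

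As groups, 9 of the 34 lists differed from other genes at 4 h in camera with the preset correlation. Interferon response genes were higher, with a positive fold change in 24 of 24 and a median log2 of 0.16 (adjusted p = 1.4e-06, and 0.637 with an estimated correlation). Extracellular matrix genes (31 of 33 positive, median 0.09), markers of preadipocytes and fibroblasts (15 of 18, 0.12), proteasome subunits (28 of 32, 0.04) and replication-dependent histones (16 of 20, 0.05) were also higher. So were targets of the integrated stress response (22 of 24, 0.05), of NRF2 (22 of 24, 0.05) and of the unfolded protein response (20 of 23, 0.04). Mitochondrially encoded proteins were lower, with 1 of 13 positive and a median of -0.06 (adjusted p = 0.0053, and 0.833 with an estimated correlation). By mean log2 CPM, the matrix, preadipocyte and integrated stress lists were higher at 4 h in all 6 replicate numbers, histones and NRF2 targets in 5, and the interferon, proteasome and unfolded protein lists in 4. The interferon rise was largest in number 6 (0.48), with falls in numbers 2 and 3 (-0.24 and -0.09). Number 3 had the largest proteasome and unfolded protein rises (0.14 and 0.13). The preadipocyte rise of 0.12 became 0.07 without number 6, in which it was 0.34 and thermogenic identity genes were lower by 0.21. Mitochondrially encoded proteins were lower in 4 numbers and higher in 3 and 4, and their difference of -0.10 became -0.04 without number 6 and -0.07 without number 1. No list held with an estimated correlation, the lowest adjusted p = 0.471 being that of the proteasome, and fry called 0. Without the block no member of these 9 lists passed over all genes or adjusted over the list alone. With the block 14 lists were called and 0 with an estimated correlation. Among the 14 was the cAMP and immediate early list, positive in 27 of 31 genes with a median of 0.13 (adjusted p = 6.7e-08, and 0.363 with an estimated correlation). By mean log2 CPM it was higher at 4 h in all 6 replicate numbers, by 0.13 ± 0.09 (SD, n = 6). Without the block that list had an adjusted p of 0.191. Leaving out 0 h replicate 4 or 4 h replicate 6 gave 14 lists.

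**Figure D2:**
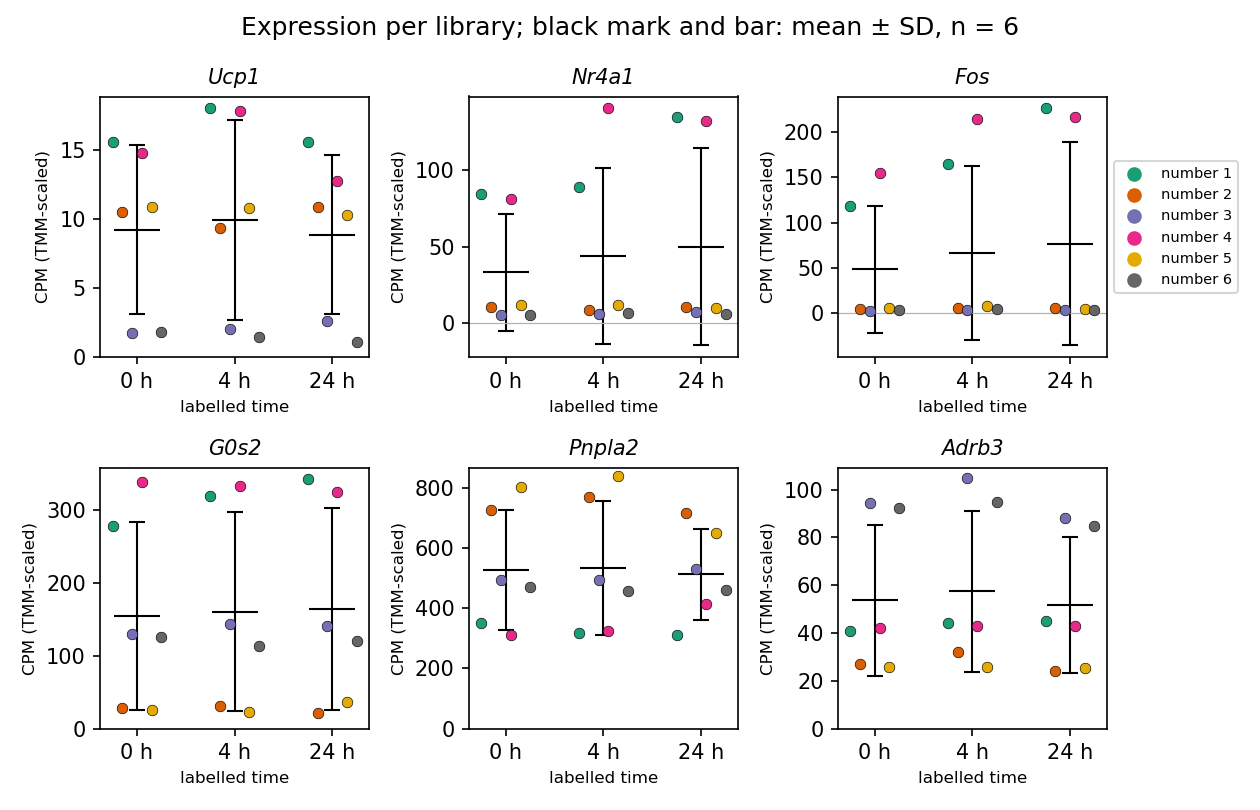
TMM-scaled CPM of Ucp1, Nr4a1, Fos, G0s2, Pnpla2 and Adrb3 in each of the 18 libraries by labelled time, coloured by replicate number, with the mean and SD of each time in black (n = 6). In Fos, 4 libraries of each time lie near 0 and those numbered 1 and 4 lie far above them.

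At 24 h the genes that stood highest over 0 h as a group were those of the interferon response, the antiviral programme. The list's mean log2 CPM was 4.93 ± 0.10 at 0 h, 5.08 ± 0.26 at 4 h and 5.36 ± 0.37 at 24 h (SD, n = 6), and it was higher at 24 h than at 0 h in all 6 replicate numbers. Ifit1, an RNA-binding antiviral protein (chromosome 19, 34640871 to 34650009), had 62.5 ± 4.44 CPM at 0 h and 102 ± 42.6 at 24 h, log2 0.70 (SE 0.20, edgeR adjusted p = 1.00). Ifit3 had 73.5 ± 6.10 and 122 ± 53.3 CPM (log2 0.72, SE 0.22), and Irf7, a transcription factor of the response, 37.5 ± 4.70 and 53.5 ± 14.02 (log2 0.50, SE 0.19). All 24 members had a positive fold change, with a median log2 of 0.40. With edgeR and no block, none passed over all genes, and 15 passed as higher adjusted over the list alone. The list was called by camera with an adjusted p of 6.7e-40 and, with an estimated correlation, 0.025. In the library 24 h replicate 5, rich in ribosomal RNA, the list had its highest level, and without that library the median was 0.31 (adjusted p = 0.042 with an estimated correlation).

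The interferon call with an estimated correlation was lost without any of 6 libraries. The adjusted p was 0.0919, 0.121, 0.0727 and 0.122 without 0 h replicates 1, 3, 4 and 6, and 0.350 and 0.0551 without 24 h replicates 2 and 4. It was 0.0832 with the block, and fry gave 0.313 without the block and 0.0472 with it.

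No gene of the 14788 passed at 24 h against 0 h with edgeR, with 158 (1.07%) at an unadjusted p under 0.05. This again lies below the share of 0.05 that chance would give, so the count of 0 is weak evidence of no change. DESeq2 and limma-voom called 0, with 211 and 154 unadjusted. Groups did not overlap for 6 genes, again fewer than the chance share of 0.216%. No anchor gene passed in these models. Nr4a1 had 50.1 ± 64.8 CPM (log2 0.61, SE 1.04) and a blocked fold change of 0.47 with a 95% interval from 0.14 to 0.79 (adjusted p = 0.421). Ucp1 had 8.87 ± 5.75 CPM, log2 -0.09 (SE 0.69), with a blocked interval from -0.24 to 0.17. The other 13 anchors tested had log2 fold changes between -0.14 (Gyk) and 0.17 (Dio2).

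With the block 1 gene passed at 24 h, Il1rl1, which encodes the receptor of interleukin 33 (chromosome 1, 40429570 to 40465415). It had 4.97 ± 3.87 CPM at 0 h and 9.02 ± 7.53 at 24 h (SD, n = 6), was higher in all 6 numbers, and had a blocked log2 fold change of 0.82 (SE 0.11, edgeR adjusted p = 0.0028). Without the block the fold change was 0.78 (SE 0.85, adjusted p = 1.00). The call was lost without 24 h replicate 2 (adjusted p = 0.139) and without 0 h replicate 6 (0.0582). In the blocked model 1155 genes (7.81%) had an unadjusted p under 0.05. The limma-voom model with the block and library weights called 58 genes, 57 higher and 1 lower, 12 of them from the interferon list. Lowest in adjusted p were the immediate early genes Fosb (log2 0.72) and Fos (0.62), both at 5.8e-05. Also higher were Ier2 (0.43, adjusted p = 0.011), Egr2 (0.32, 0.021) and the anchor Nr4a1 (0.55, 0.029). By replicate number, however, Fos and Nr4a1 were each higher at 24 h than at 0 h in only 4 of 6 and lower in 2.

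Apart from interferon, 4 lists were called at 24 h against 0 h with the preset correlation. Preadipocyte and fibroblast markers were higher in 18 of 18 genes (median 0.14, adjusted p = 2.7e-04, and 0.303 with an estimated correlation). NF-kB and cytokine genes were higher in 17 of 19 (0.14, adjusted p = 0.0058, and 0.0647 with an estimated correlation). Histones were higher in 15 of 20 (0.04, adjusted p = 0.898 with an estimated correlation) and mitochondrially encoded proteins lower, with 2 of 13 positive (-0.05, adjusted p = 0.898 with an estimated correlation). The mean of the preadipocyte list did not rise in numbers 1 and 4, and its rise of 0.17 became 0.13 without number 5, whose 24 h library is rich in ribosomal RNA and where it was largest (0.39). Mitochondrially encoded proteins were higher in number 4, and their difference of -0.08 became -0.04 without number 5 or without number 1. The NF-kB list and histones were higher in 5 of 6 numbers. The NF-kB list was lower in number 3 (-0.06), and histones were lower in number 6 (-0.12) and rose most in number 5 (0.15). Without the block no member of these 4 lists passed over all genes or adjusted over the list alone. With the block Il1rl1, a member of the NF-kB list, passed over all genes, as given above. The limma-voom model with the block and library weights called Socs3 and Ptgs2 of the NF-kB list and S100a4 and Klf2 of the preadipocyte list, all higher. The block called 14 lists, with 0 at an estimated correlation and 4 by fry. The cAMP and immediate early list was among both, with a median of 0.14 (adjusted p = 2.7e-15, fry 0.026, and 0.0709 with an estimated correlation). Its mean log2 CPM was higher at 24 h in 5 of 6 numbers, most in number 1 (0.32), and lower in number 5 (-0.11). The mean difference was 0.11 ± 0.16 (SD, n = 6). Library totals without scaling shifted the median gene by -0.17 in log2 and called 12 lists, 6 higher and 6 lower. The count was 11, 12, 3, 13 and 10 without 0 h replicates 3 and 6 and 24 h replicates 2, 4 and 6.

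**Figure D3:**
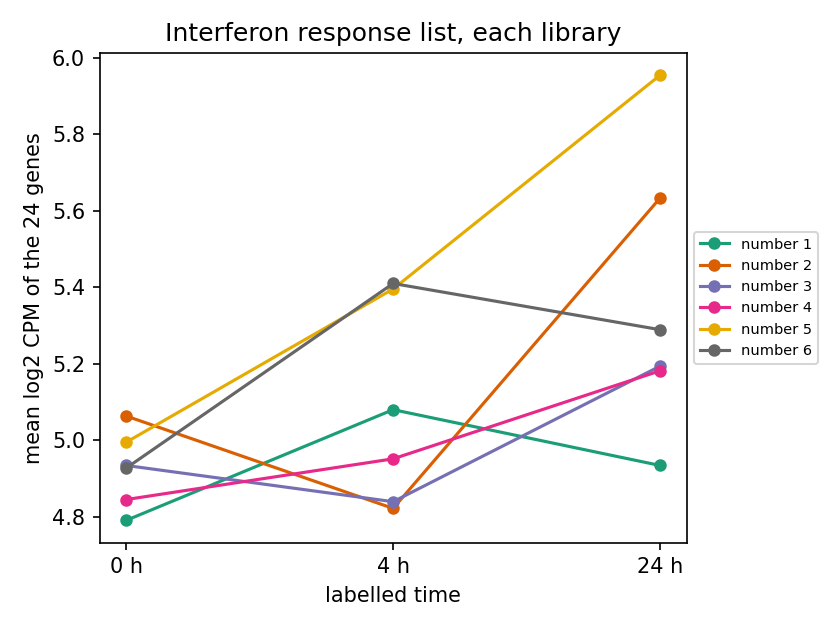
Mean log2 CPM of the 24 interferon response genes in each library against labelled time, with a line joining the libraries of each replicate number. All 6 lines lie higher at 24 h than at 0 h, and 4 of 6 lie higher at 4 h than at 0 h.

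Between 24 h and 4 h, interferon response genes were higher at the later time on average, in 24 of 24 genes with a median log2 of 0.26. The list's mean was higher in 4 of 6 replicate numbers and lower in numbers 1 and 6 (-0.15 and -0.12), with a mean difference of 0.28 ± 0.38 (SD, n = 6). The largest difference was 0.81, in number 2. This was the only list of 34 called with the preset correlation (adjusted p = 2.0e-15, and 0.608 with an estimated correlation), and fry called 0. None of its genes passed over all genes or adjusted over the list alone. No gene of 14788 passed with edgeR (137 unadjusted, 0.926%), DESeq2 (168) or limma-voom (135), nor with the block (757, 5.12%). The block called 18 lists and 0 with an estimated correlation, and library totals alone shifted the median gene by -0.16 and called 18, of which 15 were lower. The count of lists was 5, 11, 4 and 16 without 4 h replicates 2, 3, 5 and 6, and 6, 7, 3, 17, 4 and 2 without 24 h replicates 1 to 6.

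With edgeR over all 18 libraries, no gene followed any of the time patterns set beforehand (transient, sustained, late or opposed change). This held with and without the block, and no gene was called at both times in either model. The limma-voom model with the block and library weights, chosen after the data were seen, gave 6 genes the sustained pattern. That model called Fos and Fosb, among others, higher at both times. Fold changes at 4 h and 24 h correlated across genes, which are not independent replicates, with r of 0.442. Unchanged groups simulated against the same 0 h libraries gave 0.364 on average, from 0.226 to 0.489. The covariance was 0.0126, beside 0.0115 in the simulations. With the block r was 0.480, above the highest of its 20 simulations (0.369 on average, 0.476 at most), while the covariance of 0.0121 lay within theirs (0.0107 on average, 0.0146 at most). With the 0 h group split into 3 and 3 libraries, r was 0.115 and 0.117.

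Ribosomal RNA marked a single library. In 24 h replicate 5, Yam1 and Gm26917, noncoding transcripts of chromosome 17 that collect ribosomal RNA reads (Gm26917 at 39843013 to 39846341), took 41.5% of counts (Wilson interval 41.5 to 41.5), against 6.78% to 10.6% in the other 17. Mitochondrial ribosomal RNA took 18.1%, against 4.74% to 9.51%. Lars2, the gene of the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666), took 4.30% (4.28 to 4.31), against 0.0133% to 0.0253%. Mitochondrially encoded proteins took 2.91%, against 7.93% to 9.81%, and the library's total was the lowest at 7010742.

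Between groups, the number of genes detected was lower at 4 h than at 0 h, 19095 ± 682 against 19941 ± 235 (SD, n = 6, exact permutation test, p = 0.0022, adjusted p = 0.039). It was the only measure of composition to pass among 18 tests. This test ignores the pairing of libraries by number. An exact sign-flip permutation test within the 6 numbers, all lower at 4 h, gave p = 0.0312, the smallest it can give, and an adjusted p of 0.5625. The lower totals at 4 h went with it (p = 0.0281, adjusted p = 0.253, exact permutation test). Yam1 and Gm26917 took 7.21 ± 0.382%, 7.92 ± 0.832% and 13.8 ± 13.6% at 0 h, 4 h and 24 h. Of the lists for endothelium (15 genes), macrophages and leukocytes (17) and skeletal muscle (19), 4, 2 and 3 genes passed the filter, too few to test. The highest of these was Mb, myoglobin, at 40.7 ± 35.9 CPM at 0 h, 41.1 ± 37.9 at 4 h and 35.3 ± 32.3 at 24 h, a gene that brown fat also expresses.

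**Figure D4:**
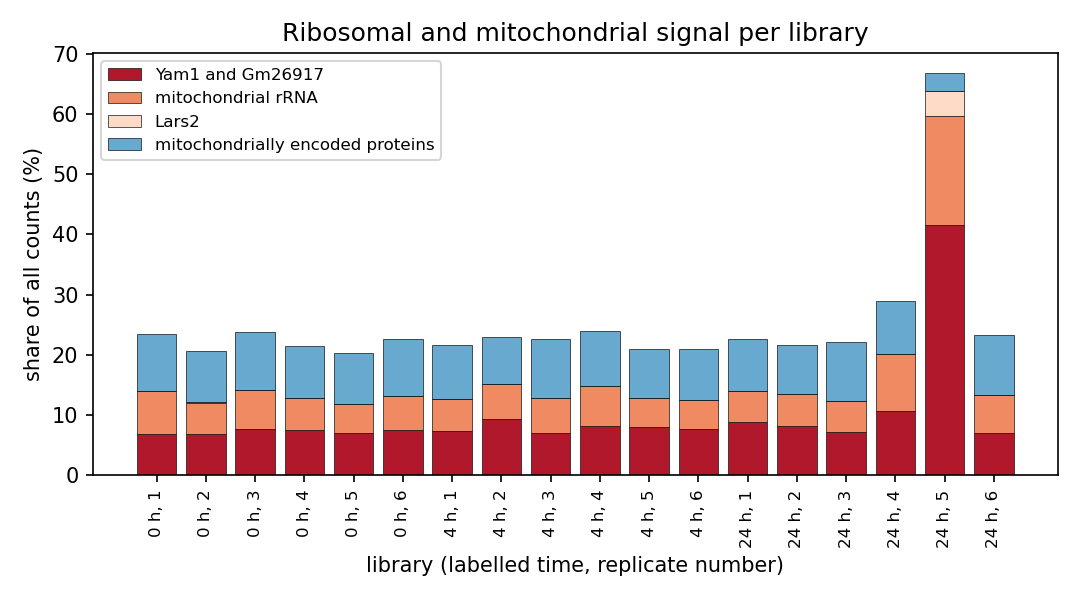
Share of all counts (%) in each library taken by Yam1 and Gm26917, mitochondrial ribosomal RNA, Lars2 and mitochondrially encoded proteins, stacked by library in order of labelled time and replicate number. The first 3 reach 41.5%, 18.1% and 4.30% in 24 h replicate 5.

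Between replicate numbers the BMC libraries differed widely. Fos had 170 ± 53.9 CPM in the libraries numbered 1 (SD, n = 3, 1 library per labelled time), 5.25 ± 0.776 in number 2, 3.19 ± 0.284 in number 3, 195 ± 34.7 in number 4, 5.72 ± 1.67 in number 5 and 3.63 ± 0.902 in number 6. Ucp1 had 16.4 ± 1.42, 10.3 ± 0.805, 2.14 ± 0.467, 15.1 ± 2.55, 10.7 ± 0.327 and 1.47 ± 0.393 CPM in the same order. With time in the model, 10716 of the 14788 genes (72.5%) differed between the 6 numbers (edgeR quasi-likelihood test), while 1 gene differed between the 3 times with number in the model. Numbers 1 and 4 differed in 1 gene, 2 and 5 in 0 (886 unadjusted) and 3 and 6 in 0 (1731 unadjusted), while each of the other 12 pairs differed in 6275 to 7381 genes. The 1 gene was the pseudogene Rps2-ps6, with 0.623 ± 0.248 CPM in number 1 and no count in number 4, and it was not called without 0 h replicate 4, 4 h replicate 1, 4 h replicate 4 or 24 h replicate 4. These comparisons were added after the data were seen.

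Number 2 against 1 showed lower genes of cholesterol synthesis and de novo lipogenesis. The transcription factors Fosb, Fos, Egr2 and Egr3, all of the immediate early class, fell, with log2 fold changes of -6.36, -5.01, -3.80 and -3.79, and Lep, the hormone leptin, fell by 4.27. Mmp11 (a matrix protease, chromosome 10, 75923222 to 75936496) was higher by 3.22 (SE 0.10), from 34.1 ± 2.59 to 320 ± 34.7 CPM (SD, n = 3), followed by Tnc (2.60), Pappa (2.46), Atoh8 (2.35) and Irf4 (2.33). Of the anchors, G0s2 (-3.59), Nr4a1 (-3.37), Dio2 (-2.80), Fgf21 (-2.20), Fasn (-1.62), Adrb3 (-0.66), Ucp1 (-0.65) and Ppargc1a (-0.23) fell. Pnpla2 (1.18), Pdk4 (0.81), Gyk (0.58) and Adipoq (0.50) rose, and Lipe, Scd1 and Cidea were not called. In all 7084 genes differed, 3480 higher and 3604 lower, and 1590 with library totals alone.

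By list, cholesterol synthesis fell in number 2, with 23 of 24 genes lower and 0 higher (median -1.20, adjusted p = 2.2e-20, and 0.022 with an estimated correlation), among them squalene epoxidase Sqle (-1.89). De novo lipogenesis fell with 19 of 21 lower and 1 higher (median -0.85, adjusted p = 1.8e-11, and 0.022 with an estimated correlation), led by Pnpla3 (-2.67) and Scd2 (-1.94). Other lists were called with the preset correlation alone. Glycolysis had 20 of 26 genes lower (Slc2a4 -1.68, Hk2 -1.60, adjusted p = 0.240 with an estimated correlation) and the integrated stress response 19 of 24 (Fgf21 -2.20, Slc7a5 -1.41, adjusted p = 0.164 with an estimated correlation). The unfolded protein response had 17 of 23 lower (Hspa5 -0.63, Dnajb9 -0.61, adjusted p = 0.490 with an estimated correlation), and triglyceride synthesis 15 of 22 (Dgat2 -1.83, Agpat2 -1.09, adjusted p = 0.240 with an estimated correlation). Cytosolic ribosomal proteins had 21 of 59 higher and 0 lower (Rps2 0.35, Rplp0 0.33, adjusted p = 0.712 with an estimated correlation). The cAMP and immediate early list had 17 of 31 lower and 10 higher (median -0.44, adjusted p = 0.0017, and 0.549 with an estimated correlation). Adjusted over the list alone, the counts were 23 lower for cholesterol synthesis, 19 lower for lipogenesis and 17 lower for the cAMP list.

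Number 3 against 1 showed lower genes of glycolysis, the integrated stress response, lipogenesis and the circadian clock. Fosb (log2 -7.96), Fos (-5.72), Mb (-4.94), Egr2 (-4.38) and Nr4a1 (-4.10, SE 0.20) fell. So did the anchors Ucp1 (-2.91), Fgf21 (-2.23), Dio2 (-2.07), Scd1 (-1.19), G0s2 (-1.18), Fasn (-1.04) and Gyk (-0.37). Adrb3 (1.14), Adipoq (0.91), Pnpla2 (0.63) and Lipe (0.21) rose, and Ppargc1a, Pdk4 and Cidea were not called. C4b, complement component 4, was highest in rank with a rise of 3.56, from 10.6 ± 1.5004 to 124 ± 13.2 CPM (SD, n = 3), followed by Cemip (2.83), St3gal6 (2.41), Grem1 (2.39) and Mmp11 (2.38). In all 7381 genes differed, 3662 higher and 3719 lower. Library totals without scaling, which shifted the median gene by 0.12, called 1870, with 1216 higher and 654 lower.

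By list, glycolysis fell in number 3, with 23 of 26 genes lower (median -1.45, adjusted p = 1.8e-15, and 0.044 with an estimated correlation), among them the lactate carrier Slc16a3 (-2.70) and Pgk1 (-2.20). The integrated stress response had 22 of 24 lower (median -0.70, Slc7a11 -2.69, adjusted p = 0.044 with an estimated correlation). Lipogenesis had 19 of 21 lower (-0.74, Scd2 -2.57, Fads2 -1.66, adjusted p = 0.019 with an estimated correlation) and the circadian clock 15 of 19 (-0.46, Bhlhe40 -1.60, Ciart -1.32, adjusted p = 0.016 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 70 of 77 lower (-0.47, Cox6a2 -2.38, Cox7a1 -0.91, adjusted p = 5.2e-19, and 0.311 with an estimated correlation). Triglyceride synthesis had 16 of 22 lower (Mogat1 -3.22, Acsl3 -1.27, adjusted p = 0.0857 with an estimated correlation). The cAMP and immediate early list had 24 of 31 lower (-1.14, adjusted p = 4.8e-12, and 0.0692 with an estimated correlation). Ribosomal proteins had 55 of 59 higher and 0 lower (median 0.36, adjusted p = 0.311 with an estimated correlation). Adjusted over the list alone, 23 genes were lower for glycolysis, 22 for the stress response, 15 for the clock and 71 for oxidative phosphorylation. Preadipocyte and fibroblast markers had a mean log2 CPM of 3.38 in number 1 and 3.75 ± 0.13 in number 3 (SD, n = 3). Matrix genes had 7.39 and 7.79, and smooth muscle markers 4.19 and 4.39 ± 0.15. Thermogenic identity genes had 4.10 and 3.86, and general adipocyte genes 6.94 and 6.89. Number 6 had 3.89 ± 0.18 for preadipocyte markers and 3.73 ± 0.12 for thermogenic identity.

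Numbers 5 and 6 were compared with the same 3 libraries of number 1. Number 5 against 1 differed in 7033 genes, 3530 higher and 3503 lower, and number 6 against 1 in 7290, 3612 higher and 3678 lower. With library totals alone, which shifted the median gene by -0.28 and 0.15, the counts were 393 higher and 1939 lower, and 1522 higher and 621 lower. Of the genes called for 2 against 1 and for 5 against 4, which have no library in common, 5686 were shared, 5685 with the same direction, where independent lists would share 802 higher and 810.1 lower. For 3 against 1 and 6 against 4, 5692 were shared, 5674 with the same direction, against 874 and 897 for independent lists. Fold changes correlated across genes with r of 0.735 and 0.812. Numbers 3 apart differed in at most 1 gene, so this agreement follows from their likeness and is no separate support. Lists called with an estimated correlation were lipogenesis and cholesterol synthesis for 5 against 1 (adjusted p = 0.027 for both), and lipogenesis, glycolysis, the integrated stress response and the clock for 6 against 1 (adjusted p = 0.016, 0.045, 0.036 and 0.012).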

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

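The tests reported in this part were chosen after the values were seen, except the search for the library closest to 24 h replicate 5. In 165 sets of 6 libraries of a labelled time, the gap between the highest or lowest library and its neighbour was set against the whole range by Dixon's ratio. It exceeded the critical value in 6 sets, and chance does so in about 1 of 20. In 24 h replicate 5, Yam1 and Gm26917 held 41.5% of counts (6.96% to 10.6% in the other 5 libraries of 24 h), mitochondrial ribosomal RNA 18.1% (5.22% to 9.51%) and the 10 most abundant genes 68.4% (22.4% to 31.03%). Mitochondrially encoded proteins held 2.91% (8.14% to 9.81%). Lipe had a log2 CPM of 8.33 in 24 h replicate 3, against 8.05 to 8.13 in the other 5. The mean log2 CPM of the mitochondrially encoded proteins was 12.01 in 0 h replicate 1, against 11.75 to 11.84 in the other 5.

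For the ribosomal RNA of 24 h replicate 5 the tables argue against RNA from a sample of a number other than 2 or 5. Across 12382 protein-coding genes its closest library was 24 h replicate 2 (r = 0.977 across genes), then 4 h and 0 h replicates 5 (0.976 and 0.974), and numbers 2 and 5 differed in 0 genes. Incomplete removal of ribosomal RNA stays a candidate, which the next values cannot decide, because the library was flagged for its high ribosomal signal. All 3 kinds of ribosomal signal lay above the highest of the other 17 libraries, by at least 1.91-fold. The folds were 3.91 for Yam1 and Gm26917 and 3.82 for 18S gene copies. No biological explanation was tested, because the design has no group for a single library.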

How the results depend on the processing

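Among the settings, the models that add the replicate block to another choice, library weights, and all comparisons between replicate numbers were chosen after the data were seen. No gene passed in any comparison of labelled times under the other scaling factors, library totals alone, the gene exclusions, DESeq2, limma-voom, both filters, the 12-library models or the threshold of 0.01. The 864 values of the anchor genes under these settings, the block and single libraries left out held none past the threshold (lowest adjusted p 0.241), and 116 had the other sign. These values leave out the limma-voom model with library weights, in which the anchor Nr4a1 passed at 24 h (log2 0.55, adjusted p = 0.029). With the replicate block 0, 1 and 0 genes passed at 4 h, 24 h and 24 h against 4 h, and 1 at 24 h also when 24 h replicate 5 or the genes resembling ribosomal RNA were left out. Limma-voom with the block and library weights called 33, 58 and 0 genes and gave 6 genes a time pattern.

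Fixed lists called at 4 h, 24 h and 24 h against 4 h were 9, 5 and 1. With library totals alone 24 h gave 12 and 24 h against 4 h 18. The replicate block gave 14, 14 and 18, and with 24 h replicate 5 left out 14, 11 and 18. An estimated correlation gave 0, 1 and 0, fry 0, 0 and 0, the block with an estimated correlation 0, 0 and 0 (also with 24 h replicate 5 left out), and the block with fry 0, 4 and 0. The cause was not tested for any of these changes. The block also took the correlation of fold changes at 4 h and 24 h from 0.442 to 0.480, past the 0.476 that its simulations reached at most.

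Leaving out each library in turn gave 0 to 1 genes at 4 h, 0 at 24 h, 0 to 1 at 24 h against 4 h and 0 to 1 genes with a time pattern, the 1 being without 4 h replicate 3. With the number in the model the ranges were 0 to 8, 0 to 14 and 0 to 1. The count of 0 at 4 h became 8 without 4 h replicate 5, 2 without 24 h replicate 3 and 1 without 0 h replicates 2 or 6 or 24 h replicate 1. The count of 1 at 24 h became 3 without 0 h replicate 1, 5, 2 and 7 without 4 h replicates 2, 5 and 6, and 14 and 12 without 24 h replicates 1 and 6. Lists called ran from 6 to 14, 3 to 13 and 1 to 17. The interferon list at 24 h kept an adjusted p between 4.6e-43 and 3.2e-18 with the preset correlation.

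Genes differing between the 6 replicate numbers ran from 8867 (stricter filter) to 11150 (limma-voom), except 4817 with library totals alone. Those totals gave 1590, 1870, 2, 2332 and 2143 genes for numbers 2, 3, 4, 5 and 6 against 1, where 24 h replicate 5, with a TMM factor of 0.430, is left unscaled. Number 4 against 1 gave 2 genes with no filter, 0 with the stricter filter, 2 with DESeq2, 0 at an adjusted p under 0.01 and 0 with ribosomal RNA share and depth as covariates. Single libraries left out gave 10272 to 10789 genes over all numbers, and 5999 to 7264, 6436 to 7522, 0 to 1, 5793 to 7135 and 6434 to 7468 for numbers 2, 3, 4, 5 and 6 against 1. Of 2906 values of genes named by number, 2867 kept side and direction, 38 missed the threshold, 1 passed it and 0 reversed. At these depths and spreads the median SE of a log2 fold change at 4 h was 0.138 without the block and 0.0619 with it, which limits what the time comparisons could detect.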

Other observations

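The tests reported in this part were chosen after the results were seen, except those of chance and of ribosomal RNA content and depth for the interferon list, and the comparisons between replicate numbers were themselves chosen after the data were seen. Lists of genes differed in how far their variance followed the replicate number. De novo lipogenesis had a median of 97.8% of a gene's variance between numbers and 0.313% between labelled times, cholesterol synthesis 97.7% and 0.456%, and glycolysis 97.7% and 0.589%. Thermogenic identity genes had 87.3% and 1.59%. At the other end were mitochondrially encoded proteins (56.0% and 5.73%), histones (57.2% and 4.98%), proteasome subunits (60.3% and 3.75%) and the interferon response (45.6% and 27.9%), whose share between times was the highest of the 34 lists.

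Single genes followed different orders over the numbers. G0s2 had 313 ± 32.3 CPM in number 1 and 26.4 ± 4.86 in number 2, with 138 ± 7.39 in number 3 (SD, n = 3). Pnpla2, whose product G0s2 inhibits, had 327 ± 22.5, 738 ± 27.3 and 506 ± 19.7 CPM. Adrb3 had 43.3 ± 2.19, 27.8 ± 4.05 and 95.9 ± 8.56 CPM, and Egr1, an immediate early transcription factor, 1171 ± 172, 171 ± 4.42 and 157 ± 7.91. Lep had 14.8 ± 0.734, 0.746 ± 0.0860 and 8.02 ± 0.377 CPM. In numbers 4, 5 and 6 the same genes had 332 ± 7.28, 28.2 ± 7.59 and 119.9 ± 6.09 (G0s2), 349 ± 55.9, 764 ± 101 and 462 ± 7.35 (Pnpla2), and 42.7 ± 0.487, 25.6 ± 0.0695 and 90.8 ± 5.15 CPM (Adrb3).

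The libraries differed by replicate number and hardly by labelled time. Depth and ribosomal RNA content as the whole cause are argued against by the 10495 genes that still differed between numbers with both as covariates, and 1 of 40 random assignments of the numbers, the real one included, gave as many as 10716 (1287 at most otherwise). Time labels attached to other libraries than those they describe are a candidate explanation, since the cAMP and immediate early list, on which norepinephrine acts, had 97.4% of its variance between numbers, at percentile 100 of 10000 random lists matched on expression. That test is not specific to the list, since lipogenesis, cholesterol synthesis, triglyceride synthesis, glycolysis and sphingolipid genes lay at percentile 100 too, while the library names in the labels run from 1 to 18 in order of labelled time and replicate number, and libraries 3 apart in that order are alike. Numbers 3 apart formed 3 pairs, with at most 1 gene differing within a pair and 6275 to 7381 between pairs. That is as many sets as the 3 labelled times, and each set holds libraries of all 3. Separate cultures or preparations behind the replicate numbers cannot be told apart from wrong time labels, because no label ties a number to a culture. No library is given another time here. If the labels are wrong, the comparisons of labelled times do not measure the response to norepinephrine.

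Interferon response genes were higher at labelled 24 h than at 0 h. A single library is argued against as the cause by a median log2 fold change of at least 0.31 whichever library was left out. The median was 0.36 with ribosomal RNA content, depth and the number in the model, against 0.39 with the number alone. With an estimated correlation the list was called in neither of these models, with adjusted p = 0.193 and 0.0832. Ribosomal RNA stood apart mainly in 24 h replicate 5 (41.5% of counts in Yam1 and Gm26917, against 6.78% to 10.6% in the others). The fit thus argues against depth and that library's ribosomal RNA as the whole cause, and says little on ribosomal RNA elsewhere. Of the 32 splits that part all 6 pairs of numbers, 1, the real split, gave a median as far from 0 (0.39, against 0.34 at most in the others), and in 1 of 32 any of the 34 lists lay as far, so chance and the choice of the list are argued against only at the smallest share that 32 splits allow. A response to norepinephrine at 24 h may account for it as a hypothesis, and anything else that differed between the labelled times, such as handling or the doubt over the labels, stays open and untested.

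Other splits of the same libraries were set beside the counts by labelled time. A real count of 0 genes is reached by every split, so 100 of 100 splits at 4 h, 24 h and 24 h against 4 h, and 32 of 32 with the block at 4 h and at 24 h against 4 h, say nothing on chance. The highest counts were 740, 922 and 2480 genes, in splits that part 0, 2 and 0 of the 6 pairs of numbers, which points to a structure of the libraries by number. Among the 32 splits that part all 6 pairs the highest was 0 in each, and with the block 1, 2 and 1. For the 1 gene at 24 h with the block, 6 of 32 splits gave as many, so chance is not excluded.

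For lists, 33 of 100 splits gave as many as 9 at 4 h (20 at most), 80 as many as 5 at 24 h (21 at most) and 98 as many as 1 at 24 h against 4 h (25 at most), so chance is not excluded over all splits. Against the splits that part all pairs, 1 of 32 gave as many as 9 at 4 h (8 at most in the others), and 17 and 30 gave as many in the other comparisons. With the block, 8 of 32 gave as many as 14 lists at 4 h (19 at most), 9 as many as 14 at 24 h (18 at most) and 1, the real split, as many as 18 at 24 h against 4 h (15 at most in the others). For genes with an unadjusted p under 0.05 with the block, 1 of 32 gave as many as 1461 at 4 h (1213 at most in the others), 4 as many as 1155 at 24 h (1386 at most) and 4 as many as 757 at 24 h against 4 h (854 at most). The interferon list had a median as far from 0 as at 4 h (0.16) in 8 of the 32 splits without the block (0.27 at most in the others), and as at 24 h against 4 h (0.26) in 5 (0.36 at most), so chance is not excluded for either. A share of 1 of 32 is the smallest these splits allow, and it was reached in some of several counts looked at.

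With 3 libraries against 3 only 10 splits exist, too few for a share under 0.05. The real split gave 7084 genes for number 2 against 1 and 7381 for number 3 against 1, each in 1 of 10 splits, with 0 at most in the others. For number 4 against 1 the real split gave 1 gene, 2 of 10 splits gave as many, and the highest other was 7.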
